A study of Homo sapiens with 6 samples.

How the data were processed

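The arrays measured total RNA of MCF-7 cells, 3 cultures transfected with miR-101 and 3 with a scrambled control, 24 h after transfection at 50 nM. Per the labels' protocols, 250 ng of total RNA per sample was amplified and labelled with biotin by in vitro transcription from the 3' end (3' IVT Express chemistry), and the transfections were independent triplicates. The groups were taken from the sample titles. The deposited values are log2 signals per probe set, 1 column per array, and per the submitters' processing notes they came from the affy software and RMA. RMA combines the probes of a set after background correction and normalization between arrays. The software version, the background setting, the probe set definition and any filter were not given in the sources used here. The log2 scale was read from the values, which ran from 5.71 to 15.27. Scale and centring of the deposited values were not stated. Array medians were 6.76, 6.77, 6.76, 6.76, 6.78 and 6.77 (miR-101 replicates 1 to 3, then control replicates 1 to 3), and the quantiles of the arrays were similar but not identical. The lowest signals are compressed near the floor of 5.71, so that folds of dim genes are understated, and no detection call came with the values.

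Of the 54675 probe sets, 62 are control probe sets. The platform's annotation table gave 1 gene symbol for 41097 probe sets and several for 1801, and the other 11721 were unnamed in that table, which does not mean that they have no gene. Symbols were looked up again through Entrez gene numbers in the RefSeq gene table of assembly GRCh38.p14, which held 41043 of the 41097, and 0 symbols changed. No coordinates are given, because the values carry no genome build. Control probe sets and probe sets with a mean below the 40th percentile of all non-control probe sets (6.60 on the log2 scale) were left out, and 32768 remained. Among probe sets with exactly 1 symbol, the one with the highest mean over all 6 arrays stood for its gene, which left 14467 genes.

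Genes were compared between miR-101 and control in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A second count asked in addition for a change of at least 1.5-fold. Changes are log2 differences, miR-101 minus control, and fold values are the higher over the lower group. Errors of single groups are SDs over 3 arrays and errors of changes are limma's standard errors.

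Gene lists, 21 in number, were written from general knowledge before the data were examined. They are the study's autophagy targets, published miR-101 targets, Polycomb repressive complex 2, core autophagy machinery, lysosome, endosomal RAB proteins and effectors, G1/S and DNA replication, G2/M and mitosis, estrogen response, interferon response, p53 targets, BCL2 family, unfolded protein and amino acid stress response, cholesterol synthesis, glycolysis and hypoxia, immediate early and growth factor response, microRNA machinery, DNA and histone methylation enzymes, luminal markers, basal and mesenchymal markers, and blood and endothelial markers. They hold 415 distinct genes, of which 363 were measured, 30 were dim and 22 had no named probe set and were not analysed here. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists, and again with an estimated correlation and with fry. Counts adjusted over the list alone used the p-values of the list's members only. A further 9 lists were added after the data were seen and are reported among the other observations.

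The genes to be named were fixed before the data were examined. They were the 10 genes lowered most and the 8 raised most among those that passed the threshold with no overlap between groups. EZH2, MCL1, FOS, STMN1, RAB5A and ATG4D were named whatever their values. For each list, the 2 called members with the largest change were named, or those with the smallest p where fewer than 2 were called. Genes named outside this rule are marked as named after their values were seen. A planned comparison of genes with miR-101 seed sites in their 3' untranslated regions, and the naming of genes by such sites, was not run, because no transcript sequence was used here.

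RNA quality was read from the 3' and 5' control probe sets of ACTB and GAPDH with an exact permutation test over 20 labelings. The limma and camera steps were tested on simulated data made from the means and spreads of these arrays, in 20 simulations of this comparison with 200 of 14467 genes changed. They recovered 50.1% of genes changed 1.25-fold, 91.3% of those changed 1.5-fold and 99% of those changed 2-fold, and 3.81% of the calls were false. For lists of 20 genes shifted by 0.3 log2 units camera called 20 of 20, and of unshifted lists 0 of 20. The simulated genes varied independently of one another and had no array-wide shift. Camera's preset correlation was therefore not put to the test, while the lysosome list, for 1, had an estimated correlation of 0.25. Its median change (-0.13) was also smaller in size than the simulated shift. The rates of false calls need not hold for the real arrays.

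Alternatives covered a replicate block, other limits for dim probe sets, a further quantile normalization, median centring, other rules for several probe sets of a gene, other variance models, array weights, each array left out in turn, an ordinary per-gene test without moderation, every probe set tested on its own, and a test against a minimum change of 1.2-fold. The ACTB 3'/5' ratio as a covariate was added after the data were seen. The mean of a list with that covariate is from ordinary least squares on the list's mean in each array. For single named genes, 17 of these settings keep limma's moderated test against no change and 1 value per gene, and calls are counted over those. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.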

Results

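Gene expression was measured in MCF-7, a human breast adenocarcinoma line that expresses the estrogen receptor, after transfection with a microRNA. MicroRNAs are short RNAs that guide Argonaute proteins to partly complementary messenger RNAs, most often in the 3' untranslated region, and lower their stability and translation. Cells received either miR-101 or a scrambled control oligonucleotide at 50 nM with a lipid reagent, and total RNA was taken 24 h later. Each oligonucleotide was transfected in 3 separate cultures, which gave 3 arrays with miR-101 and 3 with the control. The labels describe the transfections as independent, so the spread between arrays covers culture, transfection and hybridisation. The number of arrays limits the precision of all values that follow. The comparison asks which transcripts differ in amount when miR-101 is raised. In the study as recalled, it served to find targets linked to autophagy.

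The arrays were similar to one another. Their median log2 signals lay between 6.76 and 6.78, and no pair of arrays held identical values. Across all probe sets, pairs of arrays from the same group correlated with r between 0.994 and 0.997, and pairs from different groups with r between 0.992 and 0.996 (probe sets are not independent replicates). The first principal component of the gene values held 47.1% of the variance and placed all 3 miR-101 arrays (scores -12.23, -3.39 and -7.17) below all 3 control arrays (8.29, 2.44 and 12.06). As a sign of RNA quality, the signal of the 3' probe set of the ACTB control exceeded that of its 5' probe set by 1.98 ± 0.15 log2 units with miR-101 and 1.56 ± 0.41 with the control (SD, n = 3). The 6 arrays gave 2.10, 1.80 and 2.03 with miR-101 and 1.65, 1.92 and 1.12 with the control. Within each group, arrays with a higher ACTB ratio had lower scores on the first principal component. That component therefore follows RNA quality as well as the groups, and its share of variance cannot be credited to miR-101 alone. For the mean of ACTB and GAPDH the groups differed by 0.24 log2 units (two-sided exact permutation test, p = 0.2, smallest possible p 0.1). Control replicate 3 had the lowest ratio, and without it the difference was 0.09.

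The transcripts lowered most by miR-101 included POMP, TMED5, STMN1 and RAB5A. POMP, the chaperone of proteasome assembly, was 2.11-fold lower, at 11.44 ± 0.04 with miR-101 and 12.51 ± 0.05 with the control (log2 signal, mean ± SD, n = 3). TMED5, a cargo receptor between the endoplasmic reticulum and the Golgi apparatus, was 2.06-fold lower. STMN1 (stathmin, which destabilises microtubules) had a log2 signal of 9.08 ± 0.02 with miR-101 and 10.01 ± 0.02 with the control, a change of -0.93 ± 0.07 (SE). For POMP, TMED5 and STMN1 the limma adjusted p was 1.1e-05. RAB5A, the small GTPase of early endosomes, changed by -0.94 ± 0.10 (SE, adjusted p = 0.000105). NPNT, an extracellular matrix ligand of integrins, changed by -0.97, the histone variant H2AZ2 by -0.96, and the secreted glycoprotein STC1 by -0.92. The 10 genes lowered most also included NETO2, a subunit associated with kainate receptors, at -0.91, MOB4 at -0.88 and the DNA glycosylase TDG at -0.83. The rule that chose these 10 genes required the 3 miR-101 values to lie below the 3 control values. Other probe sets of these genes had smaller changes in several cases, with -0.46 for POMP, -0.11 for NPNT, -0.25 for NETO2 and -0.04 for TDG.

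Fewer transcripts rose, and by less. HEATR1, a nucleolar protein needed for ribosomal RNA synthesis, rose from 8.82 ± 0.16 to 9.60 ± 0.03 (log2 signal, mean ± SD, n = 3), which is 1.72-fold (adjusted p = 0.000117). The phospholipid flippase ATP8B1 was 1.56-fold higher (adjusted p = 0.000756) and ISOC1 1.52-fold higher (adjusted p = 0.0112). CXCR4, a chemokine receptor, rose by 0.57 log2 units and NR5A2, an orphan nuclear receptor, by 0.54. SMIM15 (0.55), the RNA-binding protein RBM24 (0.54) and the membrane metalloproteinase MMP16 (0.53) completed the 8 genes raised most. Their adjusted p-values ran from 0.000105 for NR5A2 to 0.0112 for ISOC1. Other probe sets had smaller changes, down to 0.17 for HEATR1, 0.29 for ATP8B1, 0.18 for CXCR4 and 0.05 for NR5A2. The call of MMP16, for which 4 of 5 probe sets had the same sign, ended in 1 of 17 alternative settings of the limma model (the mean of a gene's probe sets). That of RBM24 ended in 1 of the 17, with the ACTB ratio as a covariate. That of ISOC1 ended in 2, with that covariate and without control replicate 1, where its adjusted p was 0.116.

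**Figure D1:**
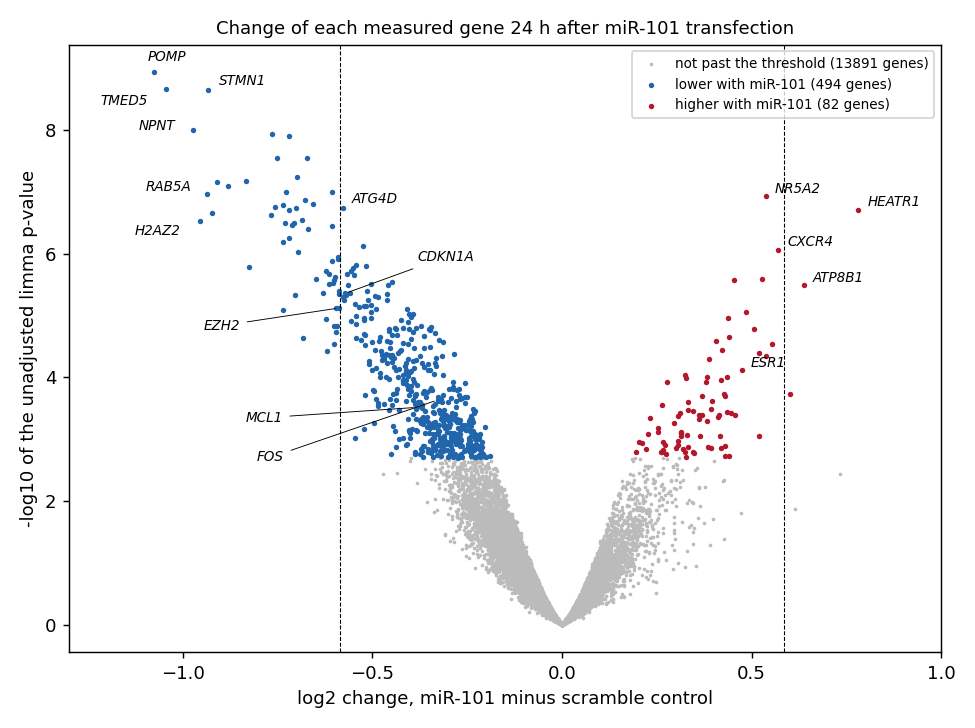
Each point is 1 of the 14467 genes tested, with the log2 change (miR-101 minus scramble control, 3 arrays each) on the horizontal axis and -log10 of the unadjusted limma p-value on the vertical axis; blue and red mark genes lower and higher at an adjusted p under 0.05, and dashed lines mark 1.5-fold. Of the called genes, 494 lie on the left and 82 on the right, and the points past 1.5-fold number 58 and 3.

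Over all 14467 genes tested, 576 (3.98%) passed an adjusted p of 0.05 in limma, of which 494 were lower and 82 higher with miR-101, so that 85.8% of them were lower. After a further quantile normalization 323 were lower and 132 higher (71.0% lower). At least 1.5-fold changes were found for 58 lowered and 3 raised genes (35 and 6 after the further quantile normalization), and at least 2-fold changes for 2 lowered genes (POMP and TMED5). The groups did not overlap in 574 of the 576 genes and in 22.3% of all genes, where chance gives 10%. Over all genes the median log2 change was -0.04. The count depended on which array was left out. Without control replicate 1 it was 200 (171 lower, 29 higher), and without miR-101 replicate 3 it was 316 (254 lower, 62 higher). It was 603 without miR-101 replicate 2. Of the raised genes alone, 48 were called without miR-101 replicate 1, 32 without control replicate 2 and 51 without control replicate 3, whose ACTB ratio was lowest. The count of genes raised at least 1.5-fold ran from 1 to 7 as single arrays were left out. It was 1 without miR-101 replicate 1, 7 without miR-101 replicate 2 or replicate 3, and 5 without control replicate 2. With the ACTB ratio of each array as a covariate, a setting chosen after the data were seen, 283 genes were lower and 40 higher. Of the 58 genes lowered at least 1.5-fold, 58 were still called lower with that covariate and 56 without control replicate 1.

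Transcripts reported as miR-101 targets fell together. Of the 17 measured members of that list, 10 were lower, 0 were higher and 7 did not pass the test, with a median log2 change of -0.47. The median was -0.28 with the mean of each gene's probe sets and -0.33 without the filter on dim probe sets. Adjusted over the list alone, 13 were lower. POMP and STC1 led the list, and ATXN1 (-0.67), SOX9 (-0.61), TGFBR1 (-0.61) and LMNB1 (-0.54), named here after their values were seen, were also lower. EZH2, the histone methyltransferase of Polycomb repressive complex 2 and a long-known miR-101 target, was at 9.56 ± 0.10 with miR-101 and 10.15 ± 0.12 with the control (log2 signal, mean ± SD, n = 3). It changed by -0.59 ± 0.09 (SE, adjusted p = 0.00132). MCL1, which blocks apoptosis, changed by -0.38 (adjusted p = 0.0154) and the transcription factor FOS by -0.33 (adjusted p = 0.0127). The 5 probe sets of MCL1 ranged from -0.62 to -0.01. The calls of MCL1 and FOS each ended in 3 of the 17 alternative settings. For MCL1 these were the fits without miR-101 replicate 1, miR-101 replicate 3 and control replicate 1 (adjusted p up to 0.0995). For FOS they included the ACTB covariate (change -0.20, adjusted p = 0.214, the highest over its alternatives) and the fit without control replicate 1. The list as a whole was lower than the other genes in limma's camera test (adjusted p = 1.16e-12; adjusted p = 0.0459 with an estimated correlation).

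The 3 transcripts that the study followed up in connection with autophagy, STMN1, RAB5A and ATG4D, were all lower, over all genes tested and adjusted over the list alone. As recalled, they were picked partly from these arrays, so neither the counts nor the test of the list are independent evidence. ATG4D, a protease that processes ATG8 proteins, was at 7.73 ± 0.04 with miR-101 and 8.31 ± 0.07 with the control (log2 signal, mean ± SD, n = 3), a change of -0.58 ± 0.06 (SE, adjusted p = 0.000117). The median of the list was -0.93 (camera adjusted p = 8.88e-09; adjusted p = 0.0459 with an estimated correlation).

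**Figure D2:**
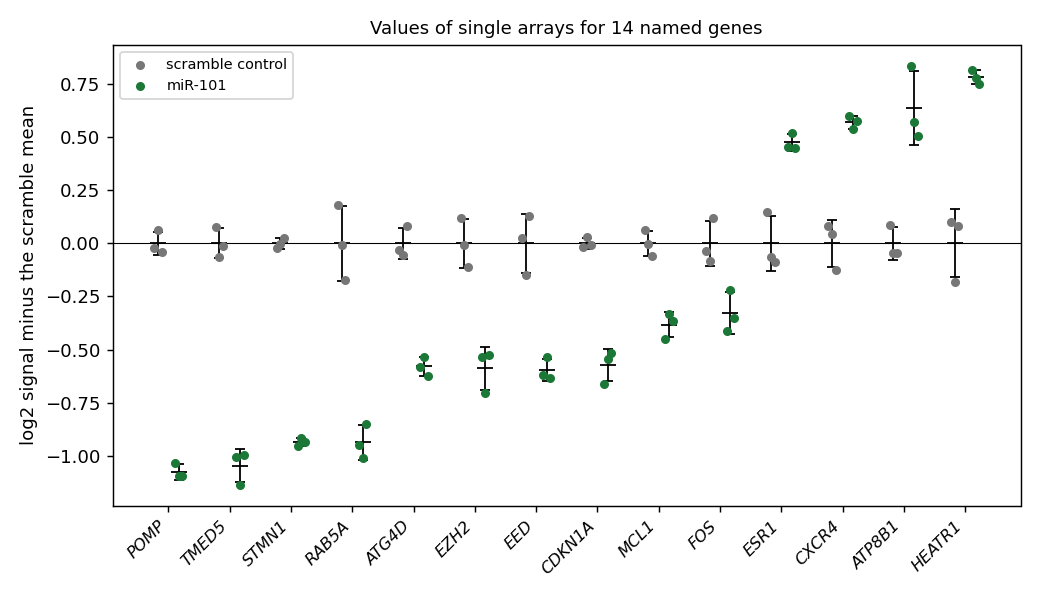
Log2 signal of each array minus the mean of the scramble control arrays for 14 named genes, with grey points for the control and green points for miR-101 (3 arrays each), horizontal ticks for group means and bars for 1 SD. POMP, TMED5, STMN1 and RAB5A lie between 0.93 and 1.08 log2 units below the control mean on average, and HEATR1 lies 0.78 above it.

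Within Polycomb repressive complex 2, which methylates histone H3, 4 of 11 measured members were lower, 0 higher and 7 did not pass, and the counts were the same adjusted over the list alone. EED, the subunit that stimulates EZH2, changed by -0.60 (adjusted p = 0.00132), although its other probe set gave 0.05. The remaining lowered members besides EZH2 were RBBP7 (-0.56) and AEBP2 (-0.34, adjusted p = 0.0409), named after their values were seen. The groups overlapped for AEBP2. The median of the list was -0.02 and it was not lower than other genes as a set (camera adjusted p = 0.251). After a further quantile normalization 3 members were lower and the median was 0.04. Among enzymes of DNA and histone methylation 1 of 21 was lower (2 adjusted over the list alone). This was the dioxygenase TET3 at -0.31 (adjusted p = 0.0305), whose call ended in 10 of the 17 alternative settings (adjusted p up to 0.154), among them the fits without each single array other than miR-101 replicate 1. The histone methyltransferase EHMT2 had a change of -0.23 that did not pass (adjusted p = 0.0658; list camera adjusted p = 0.149, and 0.0263 without the filter on dim probe sets, in a range of 0.0263 to 0.85 over camera alternatives). In the machinery of microRNA processing and silencing 1 of 14 was lower, and the same adjusted over the list alone. TNRC6B, a partner of Argonaute proteins, changed by -0.28 (adjusted p = 0.0288). Only 3 of its 6 probe sets shared that sign, and its call ended in 7 of the 17 settings (adjusted p up to 0.429), without miR-101 replicate 3, control replicate 1 and control replicate 2 among them. AGO4 had a change of -0.14 (adjusted p = 0.193), and the list did not pass camera (adjusted p = 0.606).

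Of 32 measured genes of the core autophagy machinery, a list without ATG4D (-0.58), 2 were lower, 0 higher and 30 did not pass. The share called over all genes tested was 3.98%. The counts of the list were the same adjusted over the list alone, and its median was -0.07 (camera adjusted p = 0.506). The lowered genes were the kinase ULK1, which starts autophagosome formation, at -0.29 (adjusted p = 0.0288) and the protease ATG4B at -0.30 (adjusted p = 0.0361). Their calls ended in 7 and 9 of the 17 alternative settings (adjusted p up to 0.157 and 0.223). For both these included the ACTB covariate and the fits without miR-101 replicate 1, miR-101 replicate 3, control replicate 1 and control replicate 3. Of 24 measured endosomal RAB proteins and effectors, a list without RAB5A, 2 were lower and 22 did not pass, and the same held adjusted over the list alone (camera adjusted p = 0.506). RAB4A, of recycling endosomes, changed by -0.36 (adjusted p = 0.0103), a call that ended in 3 settings (adjusted p up to 0.304), without miR-101 replicate 3 and without control replicate 1 among them. RAB14 changed by -0.32 (adjusted p = 0.0321), but its 3 probe sets ranged from -0.32 to 0.08, and with the probe set of largest spread it was 0.08. Its call ended in 11 settings (adjusted p up to 0.794), the fits without each single array among them.

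Lysosomal genes were lower as a set by a small amount. Among 21 measured members 1 was lower, 0 higher and 20 did not pass, and 2 were lower adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.0302; adjusted p = 0.85 with an estimated correlation). The sialidase NEU1 changed by -0.48 (adjusted p = 0.00692), and the membrane protein CD63 had a change of -0.28 (adjusted p = 0.0664). The list's median was -0.07 after a further quantile normalization (adjusted p = 0.0472). The ACTB ratio was higher in 2 of the 3 miR-101 arrays than in all control arrays. With it as a covariate the median was -0.06, the mean of the list differed between the groups by -0.07 ± 0.04 log2 units, beside -0.14 ± 0.05 without it (SE, 3 arrays each), the list's adjusted p was 0.425, and NEU1 no longer passed (change -0.30). Without miR-101 replicate 1 the list gave 0.198, without control replicate 3 it gave 0.0891, with array weights 0.0531 and with fry, a rotation test of the list alone, 0.075. Over its alternatives this adjusted p ran from 0.00326 to 0.85. NEU1 also lost its call without control replicate 1 (highest adjusted p over its alternatives 0.0932).

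Genes of the G1/S transition and DNA replication included 1 lowered gene among 25, and 5 adjusted over the list alone. UNG, the uracil-DNA glycosylase, changed by -0.57 ± 0.08 (SE, adjusted p = 0.000634), and RRM1, a subunit of ribonucleotide reductase, had a change of -0.34 (adjusted p = 0.0539). The median was -0.13 (camera adjusted p = 0.0629). The list passed without control replicate 2 (0.0172), without the filter on dim probe sets (0.00674) and without an intensity trend (0.0369), in a range of 0.00674 to 0.85 over its camera alternatives. Its median was smaller in other settings, at -0.07 without control replicate 3, -0.08 without miR-101 replicate 1, -0.06 after a further quantile normalization (adjusted p = 0.283) and -0.04 with the ACTB covariate (adjusted p = 0.425). With that covariate 2 members were lower and the mean of the list differed by -0.09 ± 0.04 log2 units, beside -0.12 ± 0.04 without it (SE, 3 arrays each). Among 24 genes of G2/M and mitosis 1 was lower, also adjusted over the list alone. It was the spindle kinesin KIF11 at -0.37 (adjusted p = 0.0142), whose call ended in 5 of the 17 settings (adjusted p up to 0.0771), without miR-101 replicate 3, control replicate 1 and control replicate 2 among them. CDC25C had a change of -0.20 (adjusted p = 0.152). That list had a median of 0.02 (camera adjusted p = 0.204), and a further quantile normalization gave an adjusted p of 0.0472 in the upward direction with 0 members called, within a range of 0.0472 to 0.85 over its camera alternatives. Among 17 p53 target genes 3 were lower and 0 higher, also adjusted over the list alone. The cell cycle inhibitor CDKN1A changed by -0.57 ± 0.08 (SE, adjusted p = 0.000941), TP53INP1 by -0.45 (adjusted p = 0.00397) and ZMAT3, named after its value was seen, by -0.45. A second probe set of TP53INP1 gave 0.02. The list had a camera adjusted p of 0.369. In the BCL2 family of apoptosis regulators MCL1 was the 1 lowered gene of 14, with 3 lowered when adjusted over the list alone. BCL2L1 had a change of -0.24 (adjusted p = 0.0915; list camera adjusted p = 0.506).

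The luminal identity markers of these cells went in both directions, with 1 of 18 lower and 1 higher, and 2 lower and 2 higher adjusted over the list alone. ESR1, the estrogen receptor, rose by 0.48 ± 0.09 (SE, adjusted p = 0.0058). Its 6 probe sets ranged from -0.12 to 0.48, 4 of them were positive, and the call ended with the mean of its probe sets (change 0.09, adjusted p = 0.313, the highest over its alternatives). The epithelial transcription factor ELF3 changed by -0.34 (adjusted p = 0.0139), a call that ended in 3 settings, without miR-101 replicate 1, without control replicate 1 and with the ACTB covariate. The median of the list was -0.08 with camera pointing up and fry down (camera adjusted p = 0.973). Of 22 genes of the estrogen response 0 were lower and 1 was higher, with 4 higher adjusted over the list alone. The chemokine CXCL12, ligand of CXCR4, rose by 0.31 (adjusted p = 0.0303), but its second probe set gave -0.28 and the call ended in 10 of the 17 settings (adjusted p up to 0.912), the fits without each single array among them. IGFBP4 had a change of 0.27 (adjusted p = 0.0502). The list passed camera in the upward direction (adjusted p = 0.0205; adjusted p = 0.448 with an estimated correlation), with a mean of 0.06 and a median of -0.01, so that median and test differed in sign. After a further quantile normalization the median was 0.05 and 4 members were higher. With the ACTB ratio as a covariate the adjusted p was 0.143. The median was then 0.03, and the mean differed by 0.05 ± 0.04 log2 units, beside 0.06 ± 0.03 without it (SE, 3 arrays each), so the lost call does not show that the ratio accounts for the shift. Without control replicate 3 it was 0.0573, with the mean of each gene's probe sets 0.0988, with the probe set of largest spread 0.188, without the filter on dim probe sets 0.0804 and with fry 0.156, in a range of 0.00327 to 0.448.

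Markers of other cell types that a culture could hold did not pass the test. Of 22 basal and mesenchymal markers 10 were bright enough to be measured and 0 were called by limma, with 2 lower adjusted over the list alone. CDH3 had a change of -0.27 (adjusted p = 0.0909) and TGFBI of -0.20 (adjusted p = 0.0651; list camera adjusted p = 0.772). Of 12 blood and endothelial markers 5 were measured and 0 called, also adjusted over the list alone. These were dim, with control means from 6.64 for CD14 to 7.23 for CD79A, both named after their values were seen. Signals so near the limit may not show a change. HBB had a change of 0.07 (adjusted p = 0.582) and CD3E of 0.06 (adjusted p = 0.693; list camera adjusted p = 0.54).

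Some genes of the stress and growth factor responses passed the test over all genes, and none of the metabolic and interferon lists did. In the unfolded protein and amino acid stress response 2 of 20 were lower, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.414). SEL1L, of endoplasmic reticulum associated degradation, changed by -0.46 (adjusted p = 0.00221) and DDIT4, an inhibitor of mTORC1 signalling, by -0.42 (adjusted p = 0.0316), a call that ended in 6 of the 17 settings (adjusted p up to 0.269). Of 21 immediate early and growth factor response genes 3 were lower and 1 higher, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.506). FOS and IER2 (-0.39, adjusted p = 0.0184) fell, as did JUNB (-0.28), while SPRY2, an inhibitor of growth factor signalling, rose by 0.28. JUNB and SPRY2 were named after their values were seen. JUNB lay at the threshold (adjusted p = 0.05 after rounding), and 2 members of the list, FOS and IER2, were lower after median centring and after a further quantile normalization. The call of IER2 ended in 6 settings (adjusted p up to 0.121), and for IER2 and DDIT4 alike these included the ACTB covariate and the fits without miR-101 replicate 1, miR-101 replicate 3, control replicate 1 and control replicate 3. In cholesterol synthesis 0 of 16 genes were called and 1 was lower adjusted over the list alone. PMVK had a change of -0.26 (adjusted p = 0.0608) and SREBF2 of -0.21 (adjusted p = 0.113; list camera adjusted p = 0.973). In glycolysis and the hypoxia response 0 of 24 were called by limma, also adjusted over the list alone. PKM had a change of -0.31 (adjusted p = 0.1) and HK2 of 0.23 (adjusted p = 0.171; list camera adjusted p = 0.874). Of 15 measured interferon response genes 0 were called, also adjusted over the list alone. OASL had a change of -0.11 (adjusted p = 0.399) and IRF7 of -0.08 (adjusted p = 0.401; list camera adjusted p = 0.854). By comparison, 576 of all 14467 genes tested (3.98%) passed the adjusted threshold, and 2533 had an unadjusted limma p under 0.05. The counts of the stress list (2 of 20) and of the immediate early list (3 lower and 1 higher of 21) lie above that share. They are small, and neither list passed camera (adjusted p = 0.414 and 0.506). FOS is also a member of the published target list.

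**Figure D3:**
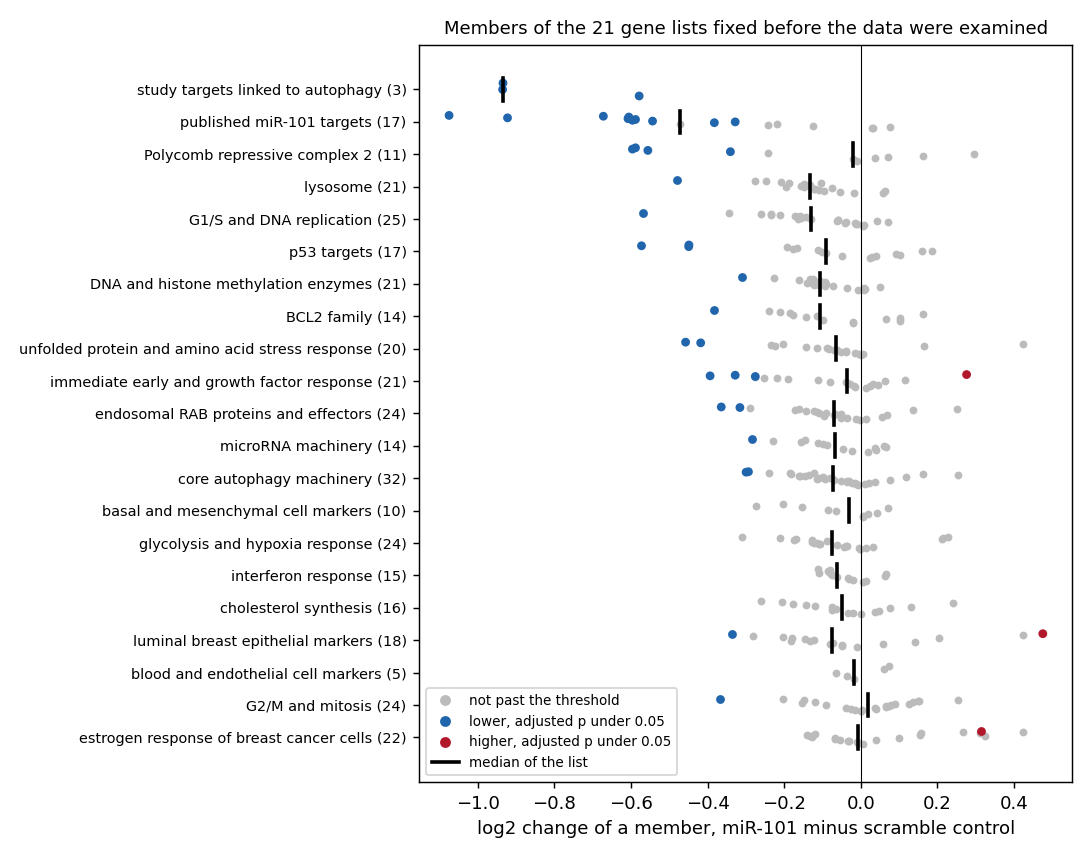
Log2 change (miR-101 minus scramble control, 3 arrays each) of each measured member of the 21 gene lists, ordered by the mean of the list, with the number of measured members in brackets; blue and red points passed an adjusted p of 0.05, grey points did not, and black bars are medians. The study's targets (median -0.93) and the published targets (median -0.47) lie apart from the other lists, whose medians lie between -0.13 and 0.02.

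Of the 21 lists 4 passed camera at an adjusted p of 0.05, and the calls of 2, the published targets and the study's targets, held with an estimated correlation. The study's targets were as recalled picked partly from these arrays, so their test is no independent evidence. The fry test, which asks whether the genes of a list move one way on balance without comparing them with other genes, passed 6 lists. Besides both target lists these were Polycomb repressive complex 2 (adjusted p = 0.0288), the interferon response (0.0228), glycolysis and hypoxia (0.0371) and the p53 targets (0.0445), each in the downward direction. After a further quantile normalization the mean change of the glycolysis and hypoxia list was 0.01. The means of the others were then smaller in size. They were -0.10 for Polycomb repressive complex 2 (-0.16 as deposited), -0.02 for the interferon response (-0.04) and -0.05 for the p53 targets (-0.10). Several members of the interferon list were dim, so its small shift rests in part on signals near the dim limit. The lists share members, since 12 genes are in more than 1 list and 7 published targets are also in another list.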

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

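In this part, the comparison with other splits of the arrays, the test of array-wide scaling and the bounds that set the published targets against the pattern were chosen after the result was seen, while the camera test of that list was planned and the bound for the RNA quality test was written before.

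Some probe sets outside the gene-level comparison passed the test. Of 6044 tested probe sets without a single gene symbol in the annotation used here, 31 (0.513%, beside 1.41% of all 32768 probe sets tested) passed limma's threshold, 22 lower and 9 higher with miR-101, and 5 of the lower and 1 of the higher ones changed at least 1.5-fold. They drew attention because 9 of them stood above the control level in data that no gene-level value uses.

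More genes were lowered than raised (494 against 82). The real count was 576 genes called, with at most 0 in the other 9 splits of the 6 arrays. The real split was thus the 1 of 10 with as many calls, and 10 splits are too few for a share under 0.05. Each other split mixes arrays of both groups, so any group difference widens its spread and few calls follow. The count also takes both directions together and cannot address the surplus of lowered genes. A difference in RNA quality as the whole cause is argued against for the genes lowered most. With the ACTB ratio as a covariate 283 genes were lower and 40 higher, and all 58 genes lowered at least 1.5-fold stayed called lower. In the replicate 2 arrays the ACTB ratios run the other way (1.80 with miR-101, 1.92 with the control). There the 87 genes lowered at least 1.5-fold in the other 4 arrays had a median log2 difference of -0.52 (86 lower). Of genes changed at any size, 492 of 645 lowered genes were lower there and 67 of 83 raised genes were higher. Over all genes 51.9% were lower in that pair (median -0.0064), beside 65.9% over all arrays. The pair therefore does not decide whether RNA quality adds to the surplus of lowered genes. Array-wide scaling stays open, since 65.9% of all genes had negative changes and the share of lowered calls moved with the scaling. After a further quantile normalization 71.0% of the called genes were lower (323 against 132, and 35 against 6 at 1.5-fold or more). With single arrays left out this share was 56.8% without miR-101 replicate 2 and 73.2% to 77.6% in the other fits. Published miR-101 targets had a median of -0.47 (-0.28 with the mean of each gene's probe sets) and passed camera with both correlations, which is consistent with direct repression by miR-101 as a hypothesis for those genes, while sites in the lowered genes were not tested.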

How the results depend on the processing

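The ACTB covariate was the 1 setting chosen after the data were seen. Of 57 named genes under up to 19 settings, 901 of 1080 values kept their side of the threshold, 154 lost the call, 24 gained one and 1 reversed. That was RAB14, at 0.085 with the probe set of largest spread. A change of sign was counted as a reversal only where the gene was called in the main fit or in the alternative. Other changes of sign are among the 901. Of 40 called named genes 22 kept their call in all 17 settings with limma's moderated test. The 576 genes called became 313 with the probe set of largest spread, 323 with the ACTB covariate, 13 with the ordinary t-test without moderation, 37 when tested against a 1.2-fold change and 873 with array weights. Leaving out single arrays gave 200 (without control replicate 1) to 603, and 316 without miR-101 replicate 3. The 61 genes changed at least 1.5-fold became 29 with the mean of a gene's probe sets, 4 with the ordinary t-test, 35 against a 1.2-fold change, 41 after a further quantile normalization and 100 when every probe set was tested. With single arrays left out they numbered 48 to 76. Of the 58 lowered ones, 55 to 58 stayed called lower in the limma settings that keep 1 value per gene, except 34 against a 1.2-fold change, and 4 did so with the ordinary t-test. The 4 list shifts became 2 with the ACTB covariate, 2 with an estimated correlation, and 2 (without control replicate 3) to 5 with single arrays left out. The RNA quality difference of 0.24 ranged from 0.09 to 0.36 with single arrays left out. A test against a 1.2-fold change is stricter by construction. For the other settings the cause was not tested.

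With the replicate number as a replicate block 523 genes were called (429 lower, 94 higher), 484 of them shared with the fit without it, and 3 lists passed, without the lysosome list (adjusted p = 0.0529). The numbers did not pair the samples. Deviations from the group means of arrays with the same number correlated at 0.032, -0.374 and -0.073. Each miR-101 array correlated best with a control array of another number. These were replicate 1 with control replicate 2 (0.388), replicate 2 with control replicate 3 (0.44) and replicate 3 with control replicate 1 (0.123). The matches follow the order of the ACTB ratio within each group, so the deviations share a structure that may reflect RNA quality, which was not tested.

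The comparison of genes with miR-101 seed sites and its alternatives were not run. Camera has no robust variance option, so that setting has no list result. No signal over background came with the values, and compressed low signals limit what can be seen for dim genes.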

Other observations

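All gene lists in this part, the genes named in it and the tests on them were chosen after the data were seen, but the bounds for the tests of proteasome subunits and of genes repressed by EZH2 were written before their results were seen.

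Some subunits of transcription and chromatin complexes were among the lowered genes. In the Mediator complex, which links transcription factors to RNA polymerase II, 3 of 28 measured genes were lower and 0 higher, also adjusted over the list alone. CDK8, its kinase, changed by -0.72 ± 0.08 (SE, adjusted p = 0.000117), MED20 by -0.42 and CDK19, the paralog of CDK8, by -0.34 (list camera adjusted p = 0.656). Of 27 measured genes of ATP-dependent chromatin remodelling complexes 3 were lower, with 7 lower and 1 higher adjusted over the list alone. SMARCA5, the ISWI ATPase, changed by -0.68 ± 0.07 (SE, adjusted p = 0.000114), ARID1A by -0.51 and SMARCD1 by -0.34 (list camera adjusted p = 0.0568). In transport from the endoplasmic reticulum to the Golgi apparatus 1 of 29 genes was lower, TMED5, and 1 higher, the coat protein SEC24A at 0.52 (adjusted p = 0.0038), also adjusted over the list alone (camera adjusted p = 0.663). Of 25 ubiquitin-conjugating enzymes UBE2F was lower (-0.44) and UBE2Q2 higher (0.33), with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.39).

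HEATR1 was the 1 called gene among 29 genes of ribosome biogenesis, also adjusted over the list alone. The list's median was 0.09, 23 of its 29 members had positive changes, and it passed camera in the upward direction (adjusted p = 7.19e-06; adjusted p = 0.762 with an estimated correlation). Of 25 cytosolic ribosomal proteins 0 were called by limma, also adjusted over the list alone (camera adjusted p = 0.451). All 25 had negative changes as deposited, with a median of -0.07, but 7 of 25 after a further quantile normalization. Among 23 genes of oxidative phosphorylation ATP5F1B, a subunit of ATP synthase, was lower by 0.70 log2 units (-0.70, adjusted p = 0.000361), the 1 call both over all genes and adjusted over the list alone. That list had a median of -0.13 (camera adjusted p = 0.0459; adjusted p = 0.879 with an estimated correlation). Its median was -0.05 after a further quantile normalization, with 16 of 23 changes negative, beside 21 as deposited.

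If the assembly chaperone POMP fell with its transcript, a compensatory rise of proteasome subunit transcripts might follow. POMP protein was not measured here. Of 28 measured subunits 0 were called, also adjusted over the list alone, and the median was -0.09 (camera adjusted p = 0.23). The mean of the list differed by -0.10 ± 0.07 log2 units between the groups (SE, 3 arrays each). That difference plus 2 standard errors is 0.04, and 0.08 after a further quantile normalization, both below the bound of 0.1 set for a rise. With 3 arrays per group, 2 standard errors are narrower than a usual confidence limit. The values as deposited speak against such a rise at 24 h. Those after that normalization lie too near the bound to decide, and array-wide scaling stays open. All 28 changes were negative as deposited and 17 after that normalization.

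With EZH2 lower, genes that it represses could rise. Among 15 measured genes reported as repressed by EZH2, 1 was higher, DKK1 at 0.39 (adjusted p = 0.00431), and 1 lower, PEBP1 at -0.33 (adjusted p = 0.0413), with 1 higher and 2 lower adjusted over the list alone. With a further quantile normalization DKK1 was at 0.43 ± 0.06 (SE, adjusted p = 0.0023, beside 0.39 ± 0.07 as deposited). PEBP1 no longer passed, at -0.26 ± 0.07 (adjusted p = 0.0725, beside -0.33 ± 0.09). The difference of the list's means was -0.033 ± 0.014 log2 units (SE, 3 arrays each; camera adjusted p = 0.964). Plus 2 standard errors this lies below the bound of 0.1 set beforehand for no rise, and so does 0.0079 after that normalization. Several members were dim, with control means of 6.63 for CDKN2B, 6.66 for CDKN1C and 6.72 for CNR1 (log2 signal, n = 3). RUNX3, CDKN2A and VASH1 were only slightly brighter. Folds of dim genes are understated, and such members pull the mean of the list toward no change. The mean therefore does not decide whether genes repressed by EZH2 rose. For single genes that bound was wrongly chosen, because DKK1 was higher with either scaling and the mean of 15 genes decides nothing about 1 of them. Whether some of them are released therefore stays open.

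Different probe sets of a gene often gave unequal changes. Of 671 other probe sets of called genes 525 (78.2%) had the same sign and 79 passed the threshold themselves. For genes changed at least 1.5-fold, 75 of 85 had the same sign and 26 passed. The 5 probe sets of TMED5 ranged from -1.05 to -0.02, and those of TDG were -0.83 and -0.04.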
